A study of Mus musculus with 7 samples.

How the data were processed

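RNA was measured in 7 subcutaneous B16mhgp100 tumours of mice treated with an antibody against PD-1, 4 with Cr1l over-expression and 3 with vector. Groups and tumour numbers were taken from the sample labels, which number the tumours 1 to 7, so replicates are separate tumours and the numbers pair nothing across the groups. The titles of Vec 6 and Vec 7 carry a further number that Vec 5 lacks. What it marks, such as a batch or a cell clone, is not given in the sources used here. Per the labels' protocols, messenger RNA was selected with poly-T beads and made into libraries that do not keep strand, so reads of a gene and of an antisense partner cannot be told apart. Per the submitters' processing notes, RSEM and DESeq2 were used with the mm39 build. Their versions, the aligner, the annotation and the read numbers are not given in the sources used here.

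The deposited expression table holds log2(TPM + 1) values per gene symbol and tumour, made by the authors from RSEM output; with the logarithm undone, the values have 2 decimals and sum to between 993520 and 996031 per tumour, which sets the unit. TPM keeps no depth, so the depth of each tumour is unknown and no counting error can be given. The deposited repertoire table holds another kind of values, which the authors made with a tool that the file name gives as MiXCR: numbers of clonotypes and clones, entropy, clonality and isotype shares per tumour, not scaled to depth, with settings not given in the sources used here. The authors' deposited table of their DESeq2 comparison gives, per the file headers, a mean normalized count (a signal on the count scale, averaged over the tumours), a log2 fold change with its standard error, a p-value and an adjusted p-value per gene. The header does not name the numerator, which was read as Cr1l from the positive sign of Cr1l itself and from the correlation with the TPM fold changes. The table names genes by Ensembl identifier, and 27182 of 28369 identifiers matched a symbol in a mouse gene name table of an older build (GRCm38), used for names alone; no coordinates are printed because that build differs from the authors' own.

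The TPM table holds 28233 genes. Genes with a mean of at least 1 TPM over the 7 tumours were tested (14954) on log2(TPM + 1) with limma 3.58.1 in R 4.3.3, using a linear model with group as the 1 term and moderated variances with a trend on mean expression. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are Cr1l minus Vec on the log2(TPM + 1) scale, which understates changes of genes with low values. Means and SD are given on the TPM scale. Single values were compared with an exact permutation test of the absolute difference of means over the 35 splits of 7 tumours into 4 and 3, two-sided, whose smallest p is 0.0286. The 20 repertoire measures had the same exact test, adjusted over the measures, on log2(value + 1) for numbers of clones and clonotypes. Measures of a chain with 0 clones in a tumour were left out for that tumour. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

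Gene lists (34 with at least 5 tested genes) were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists. The same lists were tested with a correlation estimated per list and with fry. For each list the number of genes past 0.05 adjusted over the list alone is given beside the number over all genes. Some genes stand in more than 1 list. The wording of the ribosomal list (Rpl or Rps and digits) can be read in 3 ways; a wider reading was used at first, and the literal reading with 60 genes was adopted after the results had been seen. The difference and camera adjusted p were -0.15 and 4.48e-06 with 60 genes, -0.13 and 1.56e-05 with 82, and -0.10 and 4.51e-05 with 148.

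The rule for naming genes, also fixed beforehand, takes Cr1l, up to 12 genes each way with the largest changes past the threshold and no overlap between groups, up to 4 genes of each list with the smallest p, a fixed set of immune, complement and melanocyte genes and, where fewer than 10 genes pass, the 10 with the smallest p; predicted genes and single receptor segments are skipped in the ranking. It names more genes than the text prints. Gm56655, Cry1, Cry2, Mt1, Mt2, Fkbp5, Klf9, Sgk1, Tsc22d3, Ddit4, Nr4a1, Dusp1, Dbp, Nr1d1, Per2, Mzb1, Cd46, Cr2, Cd34, mt-Atp6 and mt-Co3 lie outside it and were chosen to be named after their values were seen, whether or not the text prints them. Of these, Per2, Dbp and Nr1d1 belong to a set of 9 clock output genes and Mt1, Mt2, Fkbp5, Klf9, Sgk1, Tsc22d3 and Ddit4 form a set of 7 glucocorticoid targets. Both sets were written down after Per1, Fos, Cry1, Zbtb16, Depp1 and Pnpla2 had been seen as lower, and before the values of the members were seen. For some of them and for the clonality measures of IGL and TRB and the IgM share, the alternatives turn the sign.

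The test was tried on simulated data with the means and spreads of the real genes (14634 genes). It called 27.3% of 66 genes changed by 1 log2 unit, 84.8% of 66 changed by 2 and 93.9% of 66 changed by 4, with 4 of 14436 unchanged genes called. In simulated lists, 10 of 10 shifted lists and 0 of 20 unshifted lists were called. The simulation draws genes independently, whereas genes of real tumours vary together.

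The alternatives fixed beforehand were pseudocounts of 0.1 and 5, no filter on low values and a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, moderation without trend or with robust moderation, weights per tumour (arrayWeights), the authors' calls, and leaving out each tumour in turn. Chosen after seeing the data were the macrophage list mean as a covariate, rescaling without globin genes or without mitochondrial, globin and immunoglobulin genes, and leaving out Vec 6 and Vec 7, the tumours with the most globin RNA and with the further number in their titles. That fit keeps Vec 5 as the 1 vector tumour, which is assumed to vary like the Cr1l tumours. The macrophage list itself has no value with its own mean as covariate. The covariate is itself an outcome measured in these tumours. Count models were not run on the expression table, since it holds no counts.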

Results

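Bulk RNA was sequenced from 7 tumours of B16mhgp100, a line of the mouse B16 melanoma, grown under the skin of C57BL/6 mice. In 4 tumours (Cr1l 1 to Cr1l 4) the cells over-expressed Cr1l, which encodes Crry, a mouse membrane protein that restrains complement at the C3 convertase step, and 3 tumours (Vec 5, Vec 6 and Vec 7) were the vector controls. Every mouse received an antibody against PD-1, an inhibitory receptor of T cells, at 200 µg per dose from day 10, with 2 doses per week and 4 doses in all. The tumours were taken 1 day after the last dose. The comparison therefore asks how tumours with added Cr1l differed from vector tumours under the same antibody. No tumour without the antibody was among the samples, so its own effect was not measured. Expression was given as TPM, the relative abundance of transcripts within a tumour, which summed to between 993520 and 996031 per tumour, and between 13634 and 15352 genes reached 1 TPM in a tumour. The number of reads per tumour is not given in the sources used here.

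The tumours differed in their make-up within both groups. The titles of Vec 6 and Vec 7 carry a further number that the title of Vec 5 lacks, and what it marks is not given in the sources used here. A fit without both, added after seeing the data, keeps Vec 5 as the 1 vector tumour, which is assumed to vary like the Cr1l tumours, and it kept 14 of the 24 list calls reported below. Globin transcripts, the main RNA of red cells, took 4.14% of the TPM in Vec 6 and 0.973% in Vec 7, against 0.0106% to 0.0417% in the other 5 tumours. Transcripts of the mitochondrial genome took 7.50%, 7.60%, 8.54% and 11.7% in the Cr1l tumours and 4.49%, 7.30% and 3.58% in the Vec tumours. The first principal component held 49.5% of the variance and placed Cr1l 3 at 82.2 and Cr1l 4 at 67.1, with the other 5 tumours, of both groups, between -56.9 and -14.9. Cr1l 3 and Cr1l 4 had the highest means of the macrophage list, at 6.30 and 5.99 on the log2 scale. The list stood at 3.68 and 4.10 in Cr1l 1 and Cr1l 2 and 4.41, 3.48 and 2.93 in Vec 5, Vec 6 and Vec 7. Across 14954 genes, which are not independent replicates, Pearson's r was 0.884 to 0.974 between Cr1l tumours, 0.946 to 0.953 between Vec tumours and 0.856 to 0.960 across the groups.

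Cr1l itself stood at 76.37, 78.56, 77.91 and 83.57 TPM in the Cr1l tumours and at 52.41, 46.29 and 54.94 TPM in the Vec tumours, so that every tumour lay on the side its label gives. The means were 79.1 ± 3.12 TPM (SD, n = 4) and 51.2 ± 4.45 TPM (SD, n = 3), a log2 fold change of 0.62 (SE 0.11). The exact permutation test over the 35 splits of the 7 tumours gave a two-sided p of 0.0286, the smallest it can give, and the adjusted p over all genes was 0.119 by limma. Across the alternative limma settings the fold change was 0.55 to 0.67 and the adjusted p 0.0739 to 0.717. The authors' deposited table gave Cr1l a log2 fold change of 0.57 with an adjusted p of 0.00636.

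Per1, a light- and hormone-inducible gene of the circadian clock, fell by 2.70 on the log2 scale (SE 0.23, adjusted p = 0.0224 by limma), from 117 ± 38.2 TPM (SD, n = 3) in Vec tumours to 16.5 ± 1.69 TPM (SD, n = 4) in Cr1l tumours. The other gene past the threshold was Gm56655, a predicted gene outside the naming rule and chosen after its values were seen, which was listed at 0 in all 4 Cr1l tumours and at 8.73, 6.97 and 8.02 TPM in the Vec tumours (adjusted p = 0.0172). Its call ended without Cr1l 2 (0.107), Vec 5 (0.0565) or Vec 6 (0.0572), with no filter on low values (0.0517) and without Vec 6 and Vec 7 together (0.312), and its adjusted p ran from 6.56e-04 to 0.312 over the limma settings. Next in the ranking, without passing, stood Apln, which encodes the angiogenic peptide apelin, at 14.04, 14.5, 14.44 and 12.72 TPM against 3.33, 1.19 and 2.12 TPM, a log2 fold change of 2.27 (adjusted p = 0.0575). The remaining top-ranked genes had adjusted p of 0.0575 to 0.0702. Among them Lhfpl2 (2.31) and Mir17hg (1.36), the host gene of the miR-17-92 cluster, had positive log2 fold changes. The histone genes H2bc11 (-3.02) and H2bc18 (-2.87), Apol9b (-1.21) and Apol9a (-1.11), Pnpla2 (-0.86), the triglyceride lipase of fat stores, and Serpinc1 (-2.47), which encodes antithrombin, had negative ones. Apol9a and Apol9b are near-identical copies, as are many histone genes, so reads may be split between them in the authors' quantification.

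Of 14954 genes tested by limma, 0 were higher and 2 were lower in Cr1l tumours at an adjusted p under 0.05, while 2327 had an unadjusted p under 0.05 (1419 higher and 908 lower, against 747.7 by chance) and the authors' deposited table of their DESeq2 test called 868 higher and 416 lower. The 2 groups did not overlap for 2386 genes (1389 higher, 997 lower), or 15.96% of those tested, against 5.71% by chance. Both chance values are averages and give no spread, since genes of a tumour vary together. Other splits of the 7 tumours into 4 and 3 gave up to 3754 genes at an unadjusted p under 0.05 by limma, so neither excess excludes chance. The Per1 call ended without Cr1l 1 (adjusted p = 0.060), Cr1l 2 (0.107), Vec 5 (0.0565) or Vec 6 (0.0572) with no filter on low values (0.0864) and without Vec 6 and Vec 7 together (0.11). The adjusted p of Per1 ran from 0.00846 to 0.11 across limma alternatives, with fold changes of -2.97 to -2.46. Leaving out 1 tumour gave 0 to 2 genes higher and 0 to 6 lower, with 0 called without Cr1l 2, Vec 5 or Vec 6 and 8 without Vec 7, and median-of-ratios scaling gave 4 higher and 6 lower.

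**Figure D1:**
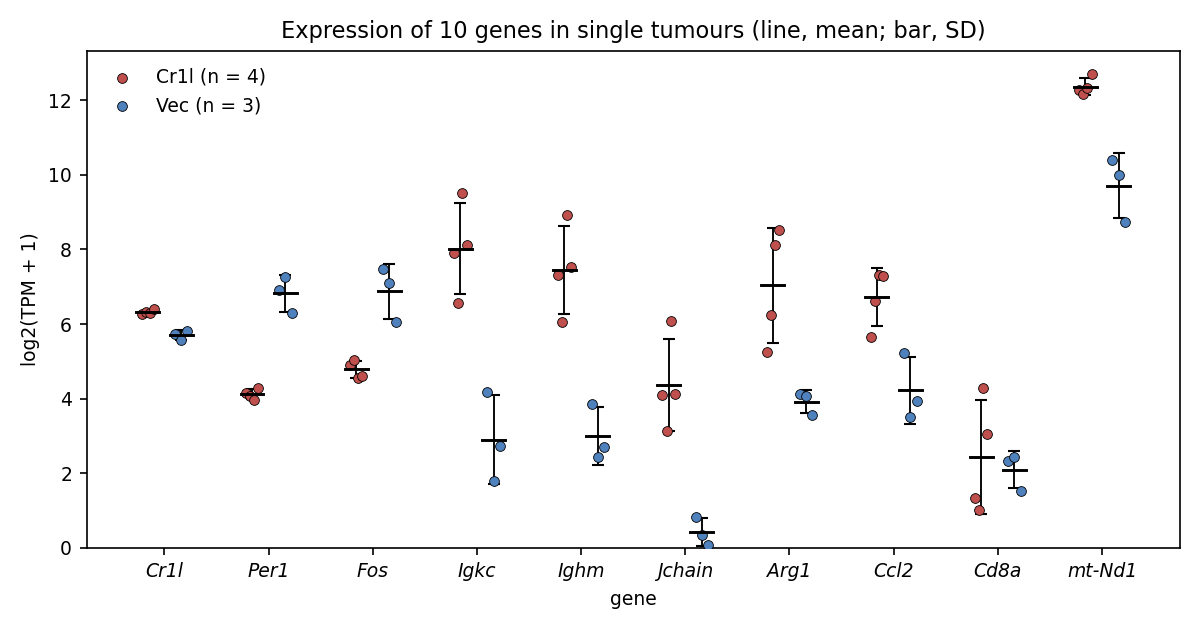
Expression of 10 genes as log2(TPM + 1) in single tumours, with Cr1l tumours (n = 4) and Vec tumours (n = 3) side by side; points are tumours, lines are means and bars are SD. The 4 Cr1l tumours lie above the 3 Vec tumours for Cr1l, Igkc, Ighm, Jchain, Ccl2 and mt-Nd1 and below them for Per1 and Fos, while the groups overlap for Cd8a.

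Among 34 gene lists fixed before the data were examined, 13 were higher and 11 lower in Cr1l tumours by camera with a preset correlation of 0.01. With a correlation estimated per list 0 of them passed (smallest adjusted p = 0.721 with an estimated correlation), and fry, which asks whether the genes of a list move one way on balance, also called 0. Over the 35 splits, 4 lists had an exact two-sided p of 0.0286, the smallest possible, and none passed once adjusted over the lists (smallest 0.243). Neither Per1 nor Gm56655 belongs to a list, so 0 members of any list passed over all genes, with 2327 genes at an unadjusted p under 0.05 by limma and 1284 called in the authors' deposited table.

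Immunoglobulin and B cell transcripts had the largest positive differences of the 34 lists on the log2(TPM + 1) scale with all 7 tumours. Over the alternatives the difference was 0.908 to 3.55 for immunoglobulin segments and 1.21 to 3.28 for B and plasma cells. Mitochondrial genes had 1.21 to 1.88, so the ranking may not hold in every setting. All 71 tested immunoglobulin segments had positive fold changes and the list mean was higher by 1.86 on the log2 scale (SE 0.71, camera adjusted p = 4.72e-12, adjusted p = 0.721 with an estimated correlation). Of these segments 6 passed when adjusted over the list alone and 0 over all genes. Segments were tested only at a mean of at least 1 TPM over the 7 tumours. Their list means were 0.33, 0.05 and 0.06 in Vec 5, Vec 6 and Vec 7, so segments passed that filter mainly through the Cr1l tumours. The count of positive segments was thus largely set by the filter and is no separate evidence, and the filter also adds to the list difference. The B and plasma cell list of 7 genes was higher by 2.56 (SE 0.62, camera adjusted p = 2.44e-05, adjusted p = 0.721 with an estimated correlation), with 5 genes higher adjusted over the list alone and 0 over all genes. Igkc, the kappa constant region, stood at 335 ± 275 TPM (n = 4) against 8.40 ± 7.71 TPM (n = 3), a log2 fold change of 5.12 (SE 0.74, adjusted p = 0.0773 by limma). Ighm, the IgM heavy chain, stood at 223 ± 182 against 7.82 ± 5.03 TPM (4.46, SE 0.64, adjusted p = 0.0773). Jchain, which joins IgM and IgA into polymers, stood at 26.7 ± 26.9 against 0.373 ± 0.376 TPM (3.93, adjusted p = 0.10). The B cell receptor gene Cd22 stood at 4.04 ± 2.84 against 0.660 ± 0.205 TPM (1.4, adjusted p = 0.270). The variable segments Igkv8-16 and Ighv1-11 averaged 60.5 and 30.9 TPM in Cr1l tumours and were listed at 0 in all 3 Vec tumours. Such segments resemble one another closely, so single ones are uncertain.

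The authors' antigen receptor table counts clones and clonotypes per tumour. Immunoglobulin heavy chain (IGH) clones numbered 484, 147, 1567 and 470 in the Cr1l tumours and 22, 0 and 6 in the Vec tumours (exact permutation test, two-sided p = 0.0286, the smallest possible). Light chain (IGL) clones numbered 734, 243, 2621 and 944 against 44, 6 and 16 (exact p = 0.0286). Clonotypes were fewer and set the groups less far apart. IGH clonotypes numbered 60, 12, 162 and 44 against 10, 0 and 3 (exact p = 0.0571). IGL clonotypes numbered 68, 20, 186 and 62 against 20, 2 and 4 (exact p = 0.0857), with Cr1l 2 and Vec 5 level at 20. T cell receptor beta (TRB) clones numbered 19, 28, 274 and 81 against 35, 25 and 17 (exact p = 0.314), and alpha (TRA) clones 20, 10, 199 and 46 against 25, 13 and 5 (exact p = 0.286). Their log2 differences of 1.23 and 1.56 were 0.50 and 0.77 without Cr1l 3. IGH clonality was 0.284 ± 0.0469 (SD, n = 4) against 0.150 ± 0.0850 (SD, n = 2; Vec 6 had 0 IGH clones), with an exact p of 0.0667, the smallest that 15 splits can give, and the difference of 0.134 was 0.0736 without Vec 5 and 0.194 without Vec 7. The share of IgM among IGH clones was 0.824 ± 0.194 (SD, n = 4) against 0.621 ± 0.300 (SD, n = 2; exact p = 0.40), and the difference of 0.202 turned to -0.00974 without Vec 5. The share of IgA was 0.0333 ± 0.0552 (SD, n = 4) against 0.333 ± 0.236 (SD, n = 2), lower in every Cr1l tumour (exact p = 0.0667, adjusted p = 0.222 to 0.444 over the settings). Its difference was -0.133 without Vec 5 and -0.467 without Vec 7, fits that leave 1 vector tumour with IGH clones, assumed to vary like the Cr1l tumours. IGH clonality and the isotype shares rest on 22 clones in Vec 5 and 6 in Vec 7, against 147 to 1567 in the Cr1l tumours. Of the 20 measures listed, 0 passed once adjusted over the measures (smallest adjusted p = 0.222), with 2 at an unadjusted exact p under 0.05. The numbers are not scaled to depth, and the table does not say whether IGL includes kappa chains.

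**Figure D2:**
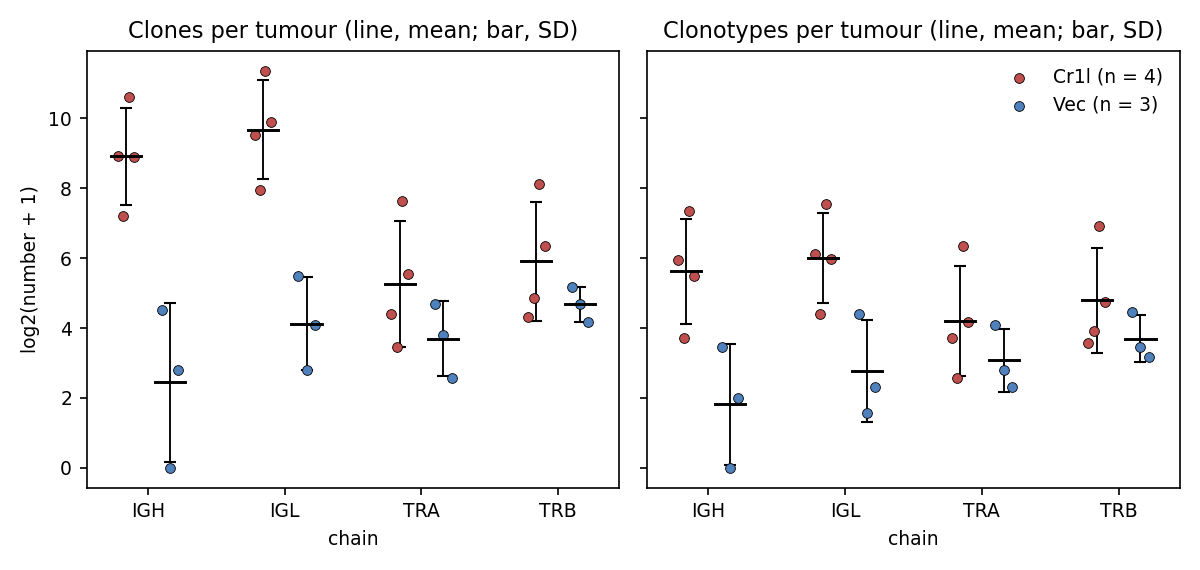
Numbers of clones and of clonotypes per tumour as log2(number + 1) for immunoglobulin (IGH, IGL) and T cell receptor (TRA, TRB) chains; points are tumours, lines are means and bars are SD. IGH clones number 147 to 1567 in the 4 Cr1l tumours and 0 to 22 in the 3 Vec tumours, while TRB clones overlap between the groups. IGL clonotypes number 20 in both Cr1l 2 and Vec 5.

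Myeloid cell genes were higher in Cr1l tumours as groups. The list of macrophages and monocytes was higher by 1.41 (SE 0.86, camera adjusted p = 7.39e-05, adjusted p = 0.721 with an estimated correlation), with 21 of 22 genes positive, 2 higher adjusted over the list alone and 0 over all genes. Arg1, the arginase of alternatively activated macrophages, stood at 189 ± 159 TPM (n = 4) against 14.4 ± 3.04 TPM (n = 3), a log2 fold change of 3.11 (adjusted p = 0.179). Nos2 of the same list stood at 25.0 ± 18.3 against 4.46 ± 4.66 TPM (2.25, adjusted p = 0.244), with groups that overlapped. The value of Arg1 therefore does not show how the macrophages were activated. Ccr2, the receptor of inflammatory monocytes, stood at 40.7 ± 37.0 against 1.79 ± 1.18 TPM (3.35, adjusted p = 0.194). Myeloid chemokines and inflammatory cytokines were higher by 1.23 (SE 0.67, camera adjusted p = 1.16e-04, adjusted p = 0.721 with an estimated correlation), with 16 of 20 genes positive, 6 higher adjusted over the list alone and 0 over all genes. The monocyte attractants Ccl7 and Ccl2 stood at 113 ± 52.8 against 17.3 ± 11.6 TPM (2.69, adjusted p = 0.119) and at 115 ± 51.6 against 20.3 ± 14.1 TPM (2.5, adjusted p = 0.136). Dendritic cell genes were higher by 1.04 (SE 0.68, camera adjusted p = 0.00104, adjusted p = 0.721 with an estimated correlation) with all 15 positive, among them Clec9a, a receptor for dead cells on cross-presenting dendritic cells (1.65), and Cd209a (2.29). Neutrophil genes were higher by 1.03 (SE 0.82, camera adjusted p = 0.0204, adjusted p = 0.721 with an estimated correlation), with 10 of 12 positive, including the gelatinase gene Mmp9 (1.61) and the receptor gene Csf3r (1.73). In the dendritic cell and neutrophil lists 0 genes passed adjusted over the list alone and 0 over all genes. The means of these 4 lists were highest in Cr1l 3 and Cr1l 4, and Cr1l 1 and Cr1l 2 lay below Vec 5 in each of them. Without Cr1l 3 the dendritic cell difference was 0.65 (adjusted p = 0.0441). The neutrophil call ended without Cr1l 3 (0.57, adjusted p = 0.206), Cr1l 4 (0.79, 0.0852) or Vec 7 (0.76, 0.121), and the difference was 1.55 (7.49e-05) without Cr1l 1. At the preset correlation the adjusted p ran over the settings from 1.19e-05 to 0.644 for dendritic cells and from 7.49e-05 to 0.348 for neutrophils. Without Vec 6 and Vec 7 together the calls of macrophages, myeloid chemokines and neutrophils ended. With the macrophage list mean as a covariate those of myeloid chemokines, dendritic cells and neutrophils ended, both settings being added after seeing the data. The calls of dendritic cells and neutrophils also ended with arrayWeights.

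Stromal genes were also higher in Cr1l tumours on average, though the list means of the groups overlapped. The fibroblast means were 4.87, 5.20, 7.09 and 6.61 in Cr1l 1 to Cr1l 4 and 5.45, 4.69 and 3.41 in Vec 5 to Vec 7 (exact permutation p = 0.20). The endothelial means were 3.60, 3.51, 5.14 and 3.20 against 3.93, 3.23 and 2.18 (exact permutation p = 0.429). Fibroblast and matrix genes were higher by 1.43 (SE 0.81, camera adjusted p = 1.56e-05, adjusted p = 0.721 with an estimated correlation), with all 24 positive, 0 passing adjusted over the list alone and 0 over all genes. The collagen genes Col3a1 and Col1a1 stood at 1351 ± 1172 against 202 ± 196 TPM (2.69, adjusted p = 0.277) and at 900.0 ± 724 against 179 ± 171 TPM (2.40, adjusted p = 0.284, and 1.59 without Vec 7). Endothelial genes were higher by 0.75 (SE 0.67, camera adjusted p = 0.0274, adjusted p = 0.749 with an estimated correlation), with 16 of 19 positive and 0 passing adjusted over the list alone or over all genes. Kdr, the main VEGF receptor of endothelium, had a log2 fold change of 1.47. Genes of hypoxia and glycolysis were higher by 0.38 (SE 0.20, camera adjusted p = 0.0213, adjusted p = 0.721 with an estimated correlation), with 18 of 25 positive and 0 passing either way. Vegfa, the growth factor of blood vessels, stood at 422 ± 153 against 182 ± 23.4 TPM (1.15, adjusted p = 0.179), and Car9, a carbonic anhydrase induced by low oxygen, had a log2 fold change of 1.24. The fibroblast difference was 0.87 (adjusted p = 0.0181) without Vec 7, and the call ended without Vec 6 and Vec 7 together (0.49, 0.112) and with the macrophage covariate (0.16, 0.346). The endothelial call ended without Cr1l 3 (0.33, adjusted p = 0.447) or Vec 7 (0.29, 0.808). The difference was 1.16 (0.00159) without Vec 5, and the call also ended with arrayWeights, with the covariate and without Vec 6 and Vec 7 together, where it turned to -0.0608 (0.696). The hypoxia call ended without Cr1l 2 (0.34, 0.0755), Cr1l 4 (0.26, 0.0852) or Vec 5 (0.35, 0.119). Over settings with the preset correlation the adjusted p was 1.12e-07 to 0.346 for fibroblasts, 0.00157 to 0.865 for endothelium and 6.58e-06 to 0.119 for hypoxia.

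Lymphocyte genes other than those of B cells gave a divided picture. NK cell genes were higher by 1.06 (SE 0.69, camera adjusted p = 0.0213, adjusted p = 0.721 with an estimated correlation), with all 7 positive, among them Ncr1, the activating receptor NKp46, at 3.23 ± 3.26 TPM (n = 4) against 0.0367 ± 0.0635 TPM (n = 3). Cytotoxic effector genes were higher by 0.75 (SE 0.69, camera adjusted p = 0.0213, adjusted p = 0.749 with an estimated correlation), with 17 of 20 positive. The chemokine genes Ccl3 (2.14) and Ccl4 (2.06) led, while Gzmb, the granzyme of killer cells, had 0.13 and the perforin gene Prf1 1.08. Of both lists 0 genes passed adjusted over the list alone or over all genes. The T cell list did not pass, at a difference of 0.56 (95% interval -1.47 to 2.59, camera adjusted p = 0.140). In it Cd4 stood at 6.79 ± 7.76 against 1.15 ± 0.708 TPM and Cd8a at 7.07 ± 8.07 against 3.45 ± 1.39 TPM. T cell receptor segments (0.60, adjusted p = 0.209), regulatory T cells (0.42, 0.196), checkpoint and exhaustion genes (0.43, 0.489), lymphoid chemokines (0.58, 0.393) and mast cells and eosinophils (0.87, 0.153) did not pass either. Adjusted over the list alone, Tnfrsf9, the costimulatory receptor 4-1BB, was the 1 regulatory T cell gene that passed (log2 fold change 1.46). In the same way 2 lymphoid chemokine genes were lower, Cxcl11 (-0.77) and Ccl21a (-3.16), with 0 in the other lists and 0 over all genes. Cd274, the ligand of PD-1, stood at 40.0 ± 18.1 against 28.2 ± 12.1 TPM (0.47). Pdcd1, PD-1 itself, stood at 3.97 ± 3.35 against 2.57 ± 1.82 TPM (0.34), and Foxp3 at 2.72 ± 3.35 against 1.02 ± 0.330 TPM (0.54). Without 1 tumour the fold change was 0.15 (Vec 7 left out) to 0.77 (Vec 5 left out) for Cd274, -0.0506 (Cr1l 3) to 0.73 (Cr1l 2) for Pdcd1, -0.25 (Cr1l 3) to 0.52 (Cr1l 1) for Gzmb, -0.29 (Cr1l 3) to 0.80 (Cr1l 2) for Cd8a, and as low as 0.0116 for Foxp3, 0.81 for Cd4 and 0.72 for Prf1 without Cr1l 3. The NK call ended without Cr1l 4 (0.90, adjusted p = 0.0679), and the cytotoxic call without Cr1l 3 (0.25, 0.580), Cr1l 4 (0.57, 0.124), Vec 5 (0.79, 0.0877) or Vec 7 (0.60, 0.133). Both calls also ended with arrayWeights and with the macrophage covariate, where the cytotoxic difference turned to -0.28 (0.0573), and the cytotoxic call ended with no filter on low values (0.0562). T cells passed as higher without Cr1l 1 (0.82, 0.0143), Cr1l 2 (0.93, 0.00132) or Vec 6 (0.67, 0.0392), while their difference was 0.00777 (0.585) without Cr1l 3 and 0.27 (0.749) without Vec 7. Regulatory T cells passed without Cr1l 1 (0.68, 0.0286) or Cr1l 2 (0.63, 0.0463) and stood at 0.0491 (0.995) without Cr1l 3 and 0.20 (0.749) without Vec 7. Receptor segments passed without Cr1l 2 (0.97, 0.00872) or Vec 6 (0.77, 0.0444) and with no filter on low values (0.27, 0.0125). Mast cells and eosinophils passed without Cr1l 1 (1.34, 0.00699) or Vec 6 (1.17, 0.0481) and stood at 0.44 (0.775) without Cr1l 3 and 0.58 (0.535) without Vec 7. Without 1 tumour checkpoint genes stood at 0.0570 (0.524, Cr1l 3 left out) to 0.82 (0.0832, Vec 5 left out) and lymphoid chemokines at 0.14 (0.838, Cr1l 3) to 0.88 (0.0794, Cr1l 1). With the macrophage covariate T cells (-0.60, 1.23e-04), regulatory T cells (-0.47, 0.0381), checkpoint genes (-0.54, 1.44e-04) and lymphoid chemokines (-0.46, 0.0388) passed as lower. Across settings with the preset correlation the adjusted p was 3.13e-04 to 0.978 for NK cells, 3.13e-04 to 0.806 for cytotoxic genes, 1.23e-04 to 0.749 for T cells, 0.0286 to 0.995 for regulatory T cells, 0.00872 to 0.919 for receptor segments, 0.00699 to 0.806 for mast cells and eosinophils, 1.44e-04 to 0.983 for checkpoint genes and 0.0388 to 0.988 for lymphoid chemokines.

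The lists of antigen presentation and interferon genes were lower in Cr1l tumours on average or did not pass. The groups overlapped in the means of the class I and type I interferon lists (exact permutation p = 0.371 and 0.314). Cr1l 3 had the highest mean of the 7 tumours in each, at 8.56 and 5.89. MHC class I presentation was lower by 0.32 on the log2 scale in Cr1l tumours (a difference of -0.32, SE 0.33, camera adjusted p = 1.11e-04, adjusted p = 0.721 with an estimated correlation), with 4 of 22 genes positive. Psmb10, a subunit of the immunoproteasome, stood at 266 ± 134 against 570 ± 75.4 TPM (-1.20, adjusted p = 0.215). B2m, the shared light chain of class I molecules, stood at 4210 ± 426 against 5907 ± 1052 TPM (-0.48, adjusted p = 0.264). Type I interferon response genes were lower (-0.24, SE 0.23, camera adjusted p = 8.51e-04, adjusted p = 0.721 with an estimated correlation), with 5 of 25 positive. Ifit3 stood at 75.1 ± 22.9 against 155 ± 15.8 TPM (-1.08, adjusted p = 0.132), while Oas2 went the other way at 39.5 ± 17.7 against 14.2 ± 3.36 TPM (1.32, adjusted p = 0.213). In the interferon list 2 genes were higher and 5 lower adjusted over the list alone, in the class I list 0, and in both 0 over all genes. The interferon gamma response did not differ by the test (-0.00, 95% interval -1.16 to 1.16, camera adjusted p = 0.140), with Socs1, a feedback inhibitor of cytokine signalling, at 1.4. MHC class II presentation did not pass either (0.58, adjusted p = 0.140), with 0 genes of either list passing adjusted over the list alone. The class I difference was -0.15 (adjusted p = 0.00626) without Cr1l 2 and -0.55 (2.26e-11) without Cr1l 3, and the type I interferon difference -0.13 (0.0177) and -0.40 (1.05e-07). The interferon gamma list passed as lower without Cr1l 3 (-0.35, 2.29e-06) and with arrayWeights (-0.31, 1.20e-04), while its difference was 0.20 (0.913) without Cr1l 2. Class II presentation passed as higher without Cr1l 1 (0.95, 0.00639) or Cr1l 2 (0.93, 0.00655) and with quantile normalization (0.53, 0.0269), and stood at 0.11 (0.995) without Cr1l 3 and 0.34 (0.549) without Cr1l 4. Both passed as lower with the macrophage covariate (-0.57, 1.19e-07 and -0.68, 3.34e-07). With the preset correlation the adjusted p over the settings was 1.97e-14 to 0.00810 for class I, 5.37e-09 to 0.0177 for type I interferon, 1.19e-07 to 0.913 for interferon gamma and 3.34e-07 to 0.995 for class II.

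Complement regulators and receptors, Cr1l left out, were higher by 1.02 (SE 0.61, camera adjusted p = 0.0271, adjusted p = 0.721 with an estimated correlation), with 11 of 14 positive and 0 passing adjusted over the list alone or over all genes. C3ar1 and C5ar1, the receptors of the anaphylatoxins on myeloid cells, stood at 31.6 ± 25.2 against 3.17 ± 2.33 TPM (2.67, adjusted p = 0.219) and at 36.5 ± 29.6 against 6.29 ± 7.58 TPM (2.42, adjusted p = 0.273). The decay-accelerating regulator Cd55 stood at 17.3 ± 15.7 against 2.82 ± 1.70 TPM (1.86), and Cd59a, which blocks the membrane attack complex, at 12.6 ± 2.97 against 13.2 ± 1.58 TPM (-0.08). Complement components did not pass (0.75, camera adjusted p = 0.196), with 0 genes adjusted over the list alone. C3, the central component, stood at 292 ± 276 against 46.8 ± 52.4 TPM (2.39) and C4b at 195 ± 141 against 108 ± 43.2 TPM (0.56). C1qa stood at 527 ± 470 against 203 ± 105 TPM (0.87) and C2 at 137 ± 30.3 against 222 ± 32.2 TPM (-0.70). The fold change of C1qa was 0.34 without Cr1l 3 and 1.4 without Cr1l 1, and that of C4b was 0.18 without Cr1l 4 and 0.94 without Cr1l 1. The regulator call ended without Cr1l 3 (0.72, adjusted p = 0.130), Cr1l 4 (0.80, 0.0904) or Vec 7 (0.83, 0.133), and also with arrayWeights, with the macrophage covariate and without Vec 6 and Vec 7 together. The components passed as higher without Cr1l 1 (1.19, 0.00961) or Cr1l 2 (1.02, 0.0382), stood at 0.37 (0.775) without Cr1l 3 and 0.40 (0.716) without Cr1l 4, and passed as lower with the macrophage covariate (-0.50, 2.11e-05). Settings with the preset correlation gave an adjusted p of 0.00350 to 0.557 for regulators and 2.11e-05 to 0.806 for components.

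Genes of the mitochondrial genome were higher by 1.58 in Cr1l tumours (SE 0.38, camera adjusted p = 3.95e-10, adjusted p = 0.721 with an estimated correlation). All 15 were positive, 11 were higher adjusted over the list alone and 0 over all genes. The complex I genes mt-Nd1, mt-Nd5 and mt-Nd6 led, with mt-Nd1 at 5329 ± 884 TPM (n = 4) against 931 ± 466 TPM (n = 3), a log2 fold change of 2.66 (adjusted p = 0.0702). The others were mt-Nd5 at 2.70 (0.112) and mt-Nd6 at 3.51 (0.118). The abundant mt-Atp6 and mt-Co3, named after their values were seen, had 0.22 and 0.19, and mt-Atp6 turned to -0.06 under quantile normalization. Without 1 tumour mt-Atp6 was 0.0480 (Vec 5 left out) to 0.54 (Vec 6 left out) and mt-Co3 -0.0125 (Vec 5) to 0.50 (Vec 6). Nuclear genes of oxidative phosphorylation went the other way (-0.12, SE 0.17, camera adjusted p = 0.0264, adjusted p = 0.749 with an estimated correlation), with 5 of 24 positive. Ribosomal protein genes were lower too (-0.15, SE 0.08, camera adjusted p = 4.48e-06, adjusted p = 0.721 with an estimated correlation), with 9 of 60 positive and Rpl13 at -0.68. In both nuclear lists 0 genes passed adjusted over the list alone and 0 over all genes. The oxidative phosphorylation call ended without Cr1l 3 (-0.06, adjusted p = 0.239), Cr1l 4 (-0.04, 0.191) or Vec 7 (-0.03, 0.461). It was -0.20 (0.00243) without Cr1l 1, -0.18 (0.00464) without Cr1l 2 and -0.20 (0.00693) without Vec 6, and the ribosomal difference was -0.09 (0.0214) without Vec 6. The oxidative phosphorylation call also ended with quantile normalization, with arrayWeights and with the macrophage covariate, where it turned to 0.12 (0.125). Both calls ended without Vec 6 and Vec 7 together. For settings with the preset correlation the adjusted p was 0.00243 to 0.585 for oxidative phosphorylation and 7.47e-10 to 0.633 for ribosomal proteins.

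Melanocyte lineage genes, which the melanoma cells carry, were lower on average (-0.32, SE 0.34, camera adjusted p = 0.00408, adjusted p = 0.721 with an estimated correlation), with 3 of 19 positive and 0 passing adjusted over the list alone or over all genes. The groups overlapped in the means of this list and of the proliferation list (exact permutation p = 0.371 and 0.571). In both, Cr1l 1 was the highest of the 7 tumours, at 8.28 and 6.73, and Cr1l 3 and Cr1l 4 were the lowest. Mc1r, the melanocortin receptor, stood at 35.7 ± 15.8 against 93.9 ± 35.4 TPM (-1.40, adjusted p = 0.222). Pmel, which encodes the melanosome protein gp100, stood at 4905 ± 2086 against 6525 ± 1638 TPM (-0.48). Tyr, the tyrosinase of pigment synthesis, stood at 136 ± 64.8 against 155 ± 35 TPM (-0.30). Pmel was -0.27 without Cr1l 3 and -0.71 without Vec 6, and Tyr was -0.08 without Cr1l 3 and -0.52 without Cr1l 1. The transcription co-regulator gene Cited1 stood at 290.1 ± 86.4 against 135 ± 12.7 TPM (1.05, adjusted p = 0.188). Proliferation genes were lower by a small amount (-0.14, SE 0.26, camera adjusted p = 0.0213, adjusted p = 0.767 with an estimated correlation), with 7 of 28 positive, 0 passing adjusted over the list alone or over all genes. Mki67, a marker of cycling cells, stood at 87.8 ± 31.2 against 88.5 ± 7.48 TPM. Genes of TGF-beta and mesenchymal change did not pass (0.38, camera adjusted p = 0.489; 0 adjusted over the list alone), with Inhba, the activin A subunit, at 2.33 and Ccn1 at -0.89. Their difference was 0.14 (0.616) without Vec 7 and 0.67 (0.0899) without Vec 5. The melanocyte call ended without Cr1l 3 (-0.14, adjusted p = 0.130), with -0.19 (0.0306) without Cr1l 4 and -0.50 (7.49e-05) without Cr1l 1. The proliferation call ended without Cr1l 3 (-0.03, 0.486), Cr1l 4 (-0.02, 0.277), Vec 5 (-0.06, 0.0877) or Vec 7 (-0.11, 0.0940). It was -0.28 (1.53e-04) without Cr1l 1, -0.24 (0.00137) without Cr1l 2 and -0.25 (0.00398) without Vec 6. The melanocyte and proliferation calls also ended with arrayWeights, and proliferation with quantile normalization. With the macrophage covariate the melanocyte difference turned to 0.16 (0.432) and proliferation passed as higher (0.20, 0.0357). In settings with the preset correlation the adjusted p was 7.49e-05 to 0.432 for the melanocyte lineage and 1.53e-04 to 0.911 for proliferation.

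Transcripts of tissues that adjoin a subcutaneous tumour were lower in Cr1l tumours on average. The groups overlapped in the means of the muscle, keratinocyte and adipocyte lists (exact permutation p = 0.0857, 0.20 and 0.571). Cr1l 3 stood above Vec 7 in each, at 4.07 against 2.47, 3.09 against 1.57 and 3.58 against 2.63. Red cell genes were lower (-3.27, SE 1.20, camera adjusted p = 1.61e-05, adjusted p = 0.721 with an estimated correlation), with 0 of 7 positive, 6 lower adjusted over the list alone and 0 over all genes. The beta globin gene Hbb-bs averaged 88.9 ± 45.6 TPM (n = 4) against 6019.6 ± 7792 TPM (n = 3). Skeletal muscle genes were lower (-2.51, SE 1.28, camera adjusted p = 3.31e-08, adjusted p = 0.721 with an estimated correlation), with 1 of 19 positive and 0 passing adjusted over the list alone or over all genes. The muscle actin gene Acta1 stood at 24.1 ± 46.8 against 266 ± 331 TPM. Keratinocyte genes were lower (-2.05, SE 1.35, camera adjusted p = 8.02e-06, adjusted p = 0.721 with an estimated correlation), with 0 of 16 positive, 1 lower adjusted over the list alone (Lgals7, 67.6 ± 7.88 against 331 ± 263 TPM) and 0 over all genes. The basal keratin gene Krt14 stood at 1.82 ± 3.58 against 78.9 ± 129 TPM, a log2 fold change of -3.34 that was -1.48 without Vec 6, which held 227.74 TPM. Adipocyte genes were lower (-0.34, SE 0.57, camera adjusted p = 0.0424, adjusted p = 0.721 with an estimated correlation), with 3 of 13 positive, 1 lower adjusted over the list alone (Pnpla2) and 0 over all genes. Vec 6 had the highest mean of all 4 lists. Without Vec 6 the muscle difference was -1.65 (adjusted p = 0.00114) and the keratinocyte difference -0.80 (0.0283), and without both Vec 6 and Vec 7, the tumours with the most globin RNA, the red cell difference was -0.70 (0.0507). The adipocyte call ended without Cr1l 1 (-0.05, 0.263), Cr1l 2 (-0.22, 0.124), Vec 5 (-0.25, 0.0811) or Vec 6 (-0.08, 0.282). It was -0.57 (0.0118) without Cr1l 3, -0.64 (0.00163) without Cr1l 4 and -0.74 (0.00177) without Vec 7. The adipocyte call also ended at a mean of 5 TPM, with median-of-ratios scaling, with quantile normalization, rescaled without globin and without Vec 6 and Vec 7 together. Among settings with the preset correlation the adjusted p was 1.79e-15 to 0.00114 for muscle, 3.95e-12 to 0.0283 for keratinocytes, 1.44e-11 to 0.0507 for red cells and 8.81e-06 to 0.282 for adipocytes.

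The list of stress and unfolded protein genes, which also holds immediate-early genes, had a lower mean in Cr1l tumours (-0.32, SE 0.10, camera adjusted p = 0.00686, adjusted p = 0.721 with an estimated correlation). In it 6 of 20 genes were positive, 2 were lower adjusted over the list alone and 0 over all genes. The members at its front were immediate-early transcription factors, which respond within minutes to growth factors and injury. Fos stood at 26.8 ± 4.53 TPM (n = 4) against 127 ± 56.6 TPM (n = 3), a log2 fold change of -2.10 (adjusted p = 0.0918). Fosb stood at 1.29 ± 0.233 against 23.6 ± 15.5 TPM (-3.11, adjusted p = 0.112) and Egr1 at 11.5 ± 6.06 against 29.8 ± 8.11 TPM (-1.41, adjusted p = 0.226). The median of the list was -0.13, and its mean difference rested on these immediate-early genes. That difference does not show that the heat shock and unfolded protein genes of the list were lower.

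**Figure D3:**
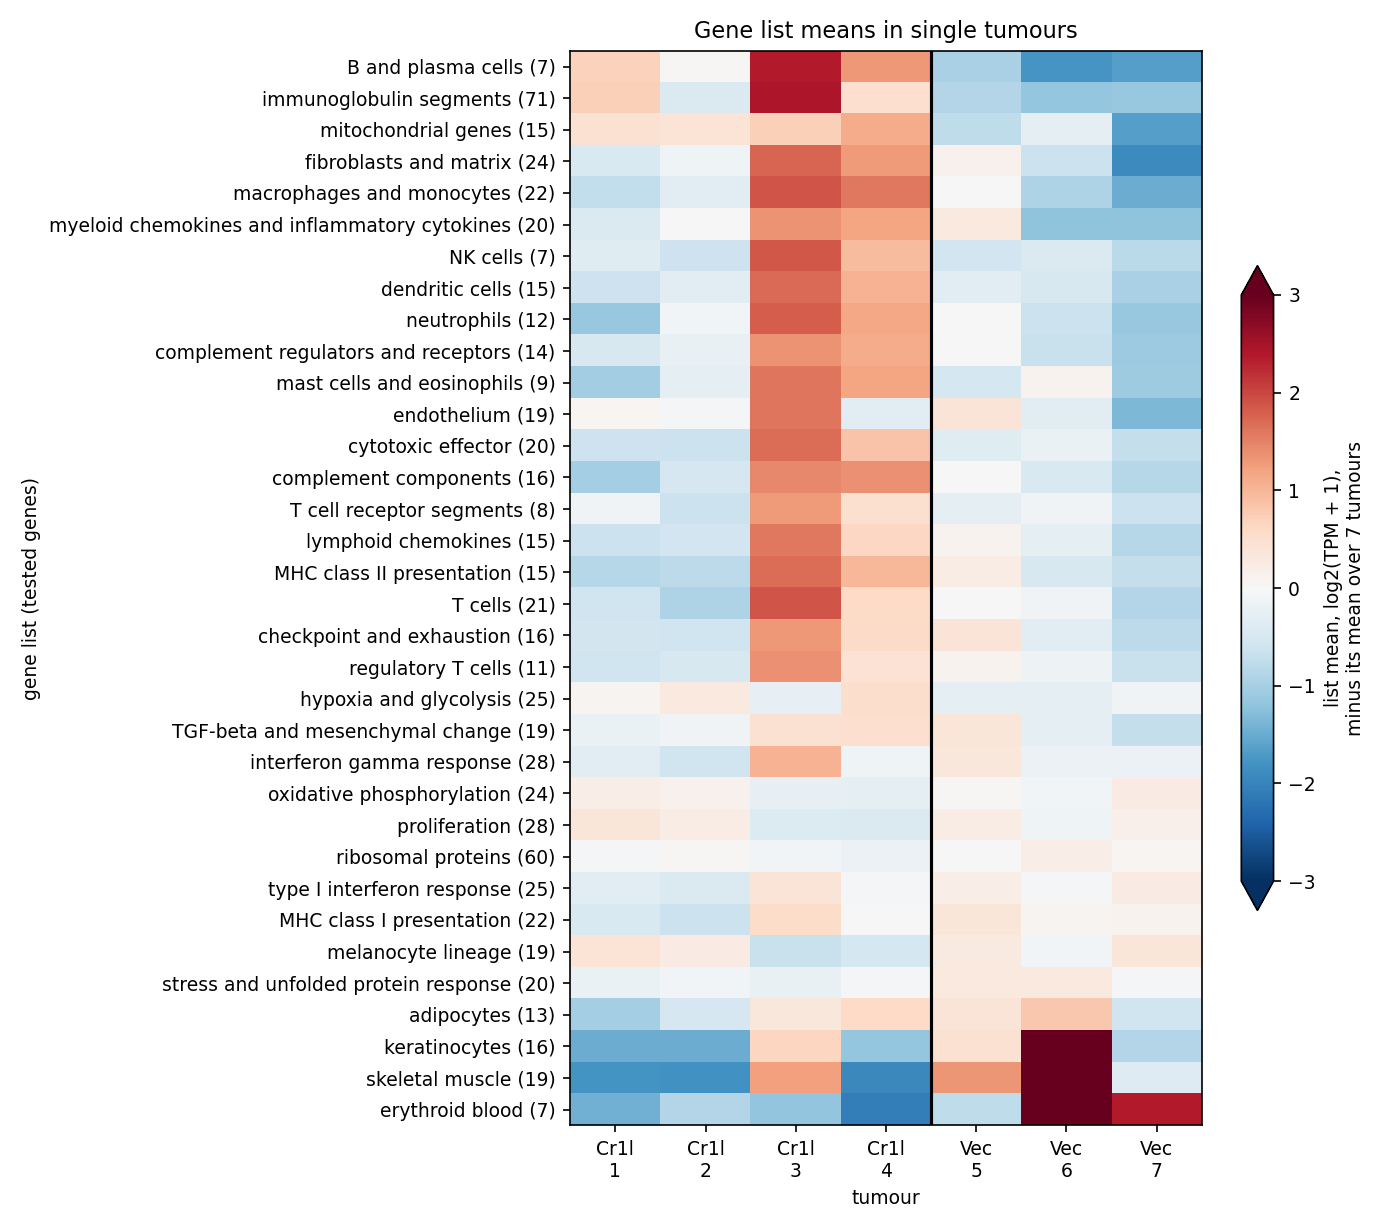
Mean log2(TPM + 1) of 34 gene lists in each of 7 tumours, minus the mean of the list over the tumours (red, above; blue, below; scale from -3 to 3), with the number of tested genes in brackets. Cr1l 3 and Cr1l 4 are above the mean in most leukocyte and stromal lists, and Vec 6 is highest in the red cell, muscle and keratinocyte lists.

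In the authors' deposited table, of 18297 genes with an adjusted p, 1284 passed (868 higher and 416 lower in Cr1l tumours), and 951 of these had an absolute log2 fold change of at least 1 in the authors' deposited table. Across 14266 genes in both, which are not independent replicates, the fold changes of the authors' deposited table and of the TPM fit had a Pearson r of 0.879. Of 1036 calls of the authors' deposited table among tested genes, 1036 had the same sign in the TPM fit, 890 had an unadjusted p under 0.05 there, 797 had groups that did not overlap and 1, Per1, passed. By list, the authors' deposited table called 17 immunoglobulin segments, 9 mitochondrial genes, 7 B and plasma cell genes (Igkc, Ighm and Jchain among them), 7 dendritic cell genes (Clec9a and Xcr1 among them), 6 macrophage genes and 6 myeloid chemokine genes, all higher. The authors' deposited table called 6 red cell genes and, of the stress list, the 3 immediate-early genes Fos, Fosb and Egr1 lower, with 1 muscle gene (Neb) and 1 keratinocyte gene (Lgals7). In the T cell list it called Cd4 alone, and in the proliferation and oxidative phosphorylation lists 0, per the authors' deposited table. Per1 had a log2 fold change of -2.90 with an adjusted p of 3.84e-18 in the authors' deposited table, and Fosb -4.26 with 2.87e-11.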

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

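The tests on immunoglobulin transcripts, on immediate-early genes and on tissue in the sample of Vec 6 were chosen after the results were seen, those on the time of day and on glucocorticoid targets after Per1, Fos, Cry1 and some glucocorticoid-responsive genes had been seen but before the values of the genes they test, and those on the globin share and on the splits of the tumours before. In 177 groups of 4 values from the Cr1l tumours, 10 had 1 tumour far from the other 3, and chance alone gives about 1 in 20 such groups. Cr1l 3 accounted for 7 of them. In Cr1l 3 Cxcl9, an interferon-induced chemokine, stood at 125.58 TPM against 17.97 to 22.98 in the others, Acta1 at 94.29 TPM against 0.12 to 1.37, Krt14 at 7.19 TPM against 0 to 0.1, and Myh1, a muscle myosin, at 6.84 TPM where the others were listed at 0. Its skeletal muscle list mean was 4.07 on the log2 scale against 0.92 to 1.06, its keratinocyte list mean 3.09 against 0.96 to 1.29, and its share of IgA among IGH clones 0.116 against 0 to 0.0132. In Cr1l 4 the 20 most abundant genes took 16.6% of the TPM against 13.5% to 13.9%, and Ccl21a, a chemokine of lymphoid tissue, stood at 1.27 TPM against 0 to 0.09. In Cr1l 1 H2bc18 stood at 0.29 TPM and was listed at 0 in the other 3.

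The first pattern is the higher immunoglobulin RNA of Cr1l tumours. Depth cancels from the log2 ratio of IGL to TRB clones within a tumour, which was higher in Cr1l tumours by 4.40 (exact permutation p = 0.0286, the smallest possible). Deeper libraries alone would not raise that ratio. Both clone numbers had been seen before the ratio was chosen, so it restates them and its p is no independent test. The same holds for the list comparisons that follow. More leukocytes of every kind would raise T cell genes alike, but the B and plasma cell list minus the T cell list was higher by 2.01 in Cr1l tumours (95% interval 1.23 to 2.78, exact p = 0.0286), and blood would bring red cell genes, whose list went the other way (-3.27, SE 1.20). The value of 2.01 rests on Igkc, Ighm and Jchain, since the 4 other genes of that list minus the T cell list gave 0.55 (-0.24 to 1.34), and for the immunoglobulin segments the test left it undecided (1.30, 0.287 to 2.31, exact p = 0.0571). More macrophages and B cells together, lymphoid tissue within the sampled tumour and an effect of Cr1l on B and plasma cells stay open, the B and plasma cell list minus the macrophage list being higher by 1.15 (-0.05 to 2.36).

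The second pattern is the lower Per1 and Fos of Cr1l tumours. The prediction for a difference in the time of day at collection was lower clock output genes. The mean of 9 of them differed by 0.0162 (95% interval -0.435 to 0.468), with the interval above the bound of -0.5 set beforehand. The interval passed that bound without Cr1l 2 (-0.515), Cr1l 3 (-0.525), Vec 5 (-0.563), Vec 6 (-0.548) or Vec 7 (-0.636). Single members moved both ways (Hlf -0.88, Ciart 0.55). A time shift that raised some of the 9 and lowered others could leave their mean near 0, so the mean does not exclude one. Cry1 and Cry2, clock genes outside that set, were lower in all 4 Cr1l tumours than in any Vec tumour. Glucocorticoid exposure before collection, which induces Per1, met its bound: the mean of 7 target genes was lower in Cr1l tumours (-0.618, 95% interval -1.06 to -0.177, exact permutation p = 0.0286, the smallest possible), and without 1 tumour it was -0.491 (Vec 5 left out) to -0.778 (Vec 7 left out) with an exact p of 0.0667 to 0.10. The 7 were Sgk1 (-0.98), Mt1 (-0.75), Fkbp5 (-0.72, and -0.44 without Vec 5), Mt2 (-0.68), Klf9 (-0.58, and -0.38 without Vec 5), Tsc22d3 (-0.58, and -0.26 without Cr1l 2) and Ddit4 (-0.05, and 0.13 without Vec 5), of which 0 passed over all genes. Mt1, Mt2, Fkbp5 and Klf9 did not overlap between the groups, while Sgk1, Tsc22d3 and Ddit4 did. Induction during dissection is left undecided by 10 other immediate-early genes (-0.462, 95% interval -1.32 to 0.391, exact p = 0.229). A difference in stress hormones, from handling or otherwise, is a candidate explanation for the lower Per1. Whether it would also account for the lower Fos was not tested. An effect of Cr1l itself was not tested apart from stress hormones and stays open.

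The third pattern is the higher skin, muscle and red cell RNA of Vec tumours. The globin share of the TPM was tested by rescaling without globin genes, and 22 of the 23 other called lists stayed called the same way. Rescaling moves the other genes of a tumour nearly alike, and camera sets a list against the other genes. The calls could therefore hardly change, so the test does not decide whether the globin share is their source. Adjacent tissue in the sample of Vec 6 was tested by leaving that tumour out: the keratinocyte difference went from -2.05 to -0.797 (adjusted p = 0.0283) and the muscle difference from -2.51 to -1.65 (adjusted p = 0.00114), so neither was kept nor lost in full. Such tissue in several samples may account for part of the pattern, and Cr1l 3 also held muscle and keratin RNA. Whether the rest goes with Cr1l or with how the tumours were dissected is open.

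The counts were compared with all 35 splits of the 7 tumours into 4 and 3. For genes higher the real count was 0, which all 35 splits reach by definition (highest other, 4), so the comparison decides nothing there. A count of genes lower as large as the real 2 came from 3 splits (highest other, 3). For lists, 10 splits gave as many higher as the real 13 (highest other, 26), and 13 splits gave as many lower as the real 11 (highest other, 26). Chance was therefore not excluded for the counts of genes lower, lists higher and lists lower. The split of Cr1l 1, Cr1l 2, Vec 5 and Vec 7 against the rest gave 3754 genes at an unadjusted p under 0.05 by limma. Cr1l 1, Vec 5, Vec 6 and Vec 7 against the rest gave 2741, and Cr1l 1, Cr1l 2, Vec 6 and Vec 7 gave 2498. Each of these is more than the 2327 of the real split. Cr1l 3, Cr1l 4, Vec 5 and Vec 6 against the rest gave 26 lists higher, so the tumours have a structure that the groups do not explain.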

How the results depend on the processing

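The macrophage covariate, the rescaled fits and the fits without Vec 6 and Vec 7 were chosen after the results were seen. Cr1l kept its direction and stayed short of the threshold in every limma setting (log2 fold change 0.55 to 0.67, adjusted p 0.0739 to 0.717), while the authors' deposited table gave it an adjusted p of 0.00636. Of 668 list results under an alternative at the preset correlation, 564 kept their sign and their side of the threshold. Of the rest 57 lost the call, 18 gained one and 29 turned sign. The tally leaves out the estimated correlation and fry, each of which called 0 of the 34 lists. Of the 24 lists called, 14 kept their call without any 1 tumour (7 higher and 7 lower), and 8 kept it in every setting in which the list was tested at the preset correlation. For single genes 2168 of 2266 results were the same, 52 turned sign, 11 lost a call and 35 gained one. Where a value moved or turned below, the cause was not tested, except that fewer tumours or genes enter some fits. The absence of read numbers limits all low values. Vec 6 and Vec 7 each carry a further number in their titles whose meaning is not given, so the fit without both sets the 1 vector tumour without it against the Cr1l tumours and assumes that it varies like them. The planned count-based fits were not run because the expression table holds no counts, the macrophage list has no value with its own mean as covariate, and no paired analysis was possible because the groups share no tumour numbers.

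Genes higher (0) became 4 with a pseudocount of 0.1, 2 with 5, 4 with median-of-ratios scaling, 6 without trend, 17 with arrayWeights, 1 with the macrophage covariate, 4 rescaled without mitochondrial, globin and immunoglobulin genes, 1 rescaled without globin, 1 without Vec 6 and Vec 7 and 868 in the authors' deposited table, with 0 to 2 without 1 tumour. Genes lower (2) became 4 with a pseudocount of 5, 0 with no filter, 1 at a mean of 5 TPM, 6 with median-of-ratios scaling, 4 with quantile normalization, 7 without trend, 17 with arrayWeights, 4 with the covariate and 416 in the authors' deposited table, with 0 to 6 without 1 tumour. The count of 0 with no filter by limma stands beside 3099 genes at an unadjusted p under 0.05. Lists higher (13) became 7 with arrayWeights, 5 with the covariate, 7 without Vec 6 and Vec 7, 0 with an estimated correlation and 0 by fry, with 8 to 18 without 1 tumour. Lists lower (11) became 15 with the covariate, 8 with quantile normalization, 7 without Vec 6 and Vec 7, 0 with an estimated correlation and 0 by fry. The correlation with the fold changes of the authors' deposited table (0.879) became 0.911 and 0.783 with pseudocounts of 0.1 and 5, 0.666 with no filter, 0.912 at a mean of 5 TPM, 0.783 with arrayWeights, 0.554 with the covariate and 0.765 without Vec 6 and Vec 7, with 0.834 to 0.874 without 1 tumour.

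With the macrophage covariate, list differences turned to 0.20 for proliferation (adjusted p = 0.0357, range 1.53e-04 to 0.911), 0.16 for the melanocyte lineage, 0.12 for oxidative phosphorylation, -0.50 for complement components, -0.60 for T cells, -0.28 for cytotoxic genes, -0.54 for checkpoint genes, -0.47 for regulatory T cells, -0.0786 for receptor segments, -0.0245 for dendritic cells, -0.28 for neutrophils, -0.27 for mast cells and eosinophils, -0.68 for class II presentation, -0.46 for lymphoid chemokines and -0.12 for TGF-beta and mesenchymal change. They turned with arrayWeights to -0.0335 for T cells, -0.0144 for checkpoint genes, -0.0552 for class II presentation and 0.0444 for proliferation, and without Vec 6 and Vec 7 to -0.11 for checkpoint genes, -0.0608 for endothelium and -0.19 for TGF-beta. The interferon gamma response turned to 0.00133 with a pseudocount of 0.1, 0.0175 at a mean of 5 TPM and 0.0310 rescaled without mitochondrial, globin and immunoglobulin genes, with -0.35 (without Cr1l 3) to 0.20 (without Cr1l 2) without 1 tumour.

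With the macrophage covariate, the log2 fold changes of genes turned to -0.84 for C1qa, -0.61 for C4b, -0.30 for Cd274, -1.07 for Cd8a, -0.81 for Cxcl9, -0.33 for Foxp3, -0.90 for Gzmb, 0.39 for Mki67, -0.71 for Pdcd1, -1.01 for Per2, 0.0869 for Pmel, 0.31 for Tyr and -0.0357 for mt-Co3. With arrayWeights they turned to -0.0651 for C4b, -0.41 for Cd8a, -0.41 for Gzmb, 0.17 for Mki67, -0.17 for Pdcd1, -0.44 for Per2, 0.0991 for Ddit4 and 0.0355 for Tyr. Without Vec 6 and Vec 7 they turned to -0.0316 for C4b, -0.13 for Cd274, -1.36 for Cxcl9, 0.20 for Dbp, 0.0156 for Nr1d1, -0.42 for Pdcd1 and -0.45 for Per2. Quantile normalization gave -0.0736 for Cd46, -0.0247 for Per2 and -0.0559 for mt-Atp6, a pseudocount of 0.1 gave -0.13 for Per2, and rescaling without mitochondrial, globin and immunoglobulin genes gave 0.0145 for Dbp. Without 1 tumour the ranges that cross 0 were -0.29 to 0.80 for Cd8a, -0.28 to 1.46 for Cxcl9, -0.20 to 0.21 for Dbp, -0.29 to 0.13 for Ddit4 (highest without Vec 5), -0.25 to 0.52 for Gzmb, -0.25 to 0.0925 for Mki67 (highest without Cr1l 3), -0.42 to 0.11 for Nr1d1, -0.0506 to 0.73 for Pdcd1, -0.62 to 0.51 for Per2 and -0.0125 to 0.50 for mt-Co3. The clonality difference was -0.0122 to 0.199 for IGL (IGL_Clonality) and -0.0307 to 0.0152 for TRB (TRB_Clonality), and that of the IgM share -0.00974 (without Vec 5) to 0.415 (without Vec 7), each leaving 1 vector tumour with IGH clones, which is assumed to vary like the Cr1l tumours. None of these genes was called in the full data.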

Other observations

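Cry1, Cry2, Per2, Dbp, Nr1d1, Nr4a1 and Mt2 are named here after their values were seen, although the sets that hold Per2, Dbp, Nr1d1 and Mt2 were fixed before, and the covariate fit was added after the results were seen. Clock repressor genes beside Per1 also had low values in Cr1l tumours: Cry1 stood at 8.73 ± 1.07 TPM (SD, n = 4) against 21.9 ± 5.22 TPM (SD, n = 3), a log2 fold change of -1.22 (adjusted p = 0.10 by limma), and Cry2 at 7.74 ± 0.591 against 23.9 ± 9.39 TPM (-1.43, adjusted p = 0.127). Cry2 passed without Vec 7 (-1.80, adjusted p = 0.0431, over a range of 0.0431 to 0.407), and Cry1 passed in no limma setting (0.0514 to 0.518). Both are repressors of the clock loop, as is Per2, which stood at 3.87 ± 6.14 against 1.79 ± 1.08 TPM (0.14, turning to -0.0247 under quantile normalization and to -0.62 without Cr1l 4). The clock outputs Dbp (-0.02) and Nr1d1 (-0.21) had fold changes near 0, Dbp turning to 0.0145 when rescaled without mitochondrial, globin and immunoglobulin genes. Nr4a1, an immediate-early nuclear receptor, stood at 65.6 ± 16.2 against 154 ± 25.1 TPM (-1.24, adjusted p = 0.109), and the metallothionein gene Mt2 at 1598 ± 165 against 2559 ± 181 TPM (-0.68, adjusted p = 0.120). In the authors' deposited table the adjusted p was 3.91e-08 for Cry1, 5.93e-05 for Cry2, 1.73e-05 for Nr4a1 and 0.00198 for Mt2.

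With the macrophage list mean as a covariate, 12 of the 23 called lists that it can test kept their call and 7 lists not called before passed as lower, each with a difference of the other sign before except the interferon gamma response, among them T cells (-0.60, adjusted p = 1.23e-04), MHC class II presentation (-0.68, 3.34e-07), the interferon gamma response (-0.57, 1.19e-07), checkpoint and exhaustion genes (-0.54, 1.44e-04) and complement components (-0.50, 2.11e-05). Over the settings with the preset correlation, the adjusted p was 1.23e-04 to 0.749 for T cells, 3.34e-07 to 0.995 for class II, 1.19e-07 to 0.913 for interferon gamma, 1.44e-04 to 0.983 for checkpoint genes and 2.11e-05 to 0.806 for components. The covariate is an outcome of the same 7 tumours, so these values describe T cell and interferon genes at a given macrophage level and test no mechanism.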
